A study of Mus musculus with 6 samples.

How the data were processed

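RNA of mouse midbrain was compared on two-colour oligonucleotide arrays printed in-house. Per the labels' protocols, total RNA was extracted with TRIzol and reverse transcribed with oligo dT and random primers in the presence of aminoallyl-dUTP, and the cDNA was coupled to Cy3 or Cy5. Per the series' design, collagen and control RNA were hybridised together, with 3 biological replicates and a technical dye swap of each. Groups came from the labels' channel sources and replicate numbers from the sample titles. The labels describe intradermal injection, while the series title names a subcutaneous one. Their wording of the time of sacrifice is unclear.

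The scan tables hold deposited spot intensities of channels A and B, background-corrected by the authors' quantification software per the file headers, on a linear scale and not normalised. The software, scanner settings and meaning of the spot flags are not given in the sources used here. Each of the 6 arrays came as 2 or 3 tables, 16 in all, with 10080 spots in 48 printing blocks. Log ratios of tables of 1 array correlated at 0.62 to 0.90, and they were treated as repeat scans. A rejected channel is listed at intensity 0. Both channels were measured in 57.8% to 86.4% of the spots of a scan, the lowest share being on the collagen_in_Cy3 array of replicate 2. That array also had the widest log2 ratios, with an SD of 0.78 against 0.36 to 0.51 on the others. The precision is limited by the number of arrays.

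A second table holds the authors' deposited log ratios, 1 column per array, read here as log2 values. Its log base, centring and direction are not stated. Set against the scans with spots ordered by printing block, its columns correlated at 0.65 to 0.80 with the turned log ratios, and at −0.0084 to 0.032 in the order in which spots lie on the slide. With loess within printing blocks the correlations were 0.77 to 0.91, and slopes among the brightest spots were 0.62 to 0.83. All 6 columns ran the same way, as collagen over control if channel A is Cy3. The column medians were 0.0021, −0.0018 and −0.00067 for collagen_in_Cy5 replicates 1, 2 and 3, and 0.0017, 0.00087 and −0.0024 for collagen_in_Cy3. The scale and centring of this table stay unknown, and it served only as an alternative. Probe genes came from the platform annotation: 9066 probes had 1 gene, 12 several and 1002 none listed. Of the first, 8977 were found by gene identifier in the RefSeq table of GRCm38.p6, which was used for names only. No genome build is named by the files, so no coordinates are given. Control spots could not be told from other unnamed probes and were kept as unnamed.

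The corrected intensities were used as deposited, without normexp, because the columns already were corrected. Spots with either channel at 0 were missing. Log2 of channel B over channel A was normalised within each scan by global loess (span 0.3, 4 iterations), and scans of an array were averaged. Ratios were turned to collagen over control, and the 2 arrays of a replicate were averaged, so that n = 3 and a dye effect of equal size on both arrays cancels. Probes measured on all 6 arrays were fitted with limma 3.58.1 (lmFit, eBayes, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3, with statmod 1.5.0 for blocked fits. The p-values are two-sided. Since replicates are not stated to be single animals, they measure the spread between these samples. Scores in local SD units used a window of 500 probes of similar intensity and a limit of 2. Gene lists with 5 or more measured members were tested with camera at a preset correlation of 0.01, each gene by its probe of highest mean intensity. Of 122 genes with more than 1 tested probe, 57 had probes of opposite sign. The channel component is the mean of channel B over channel A over both arrays of a replicate, tested in the same way. Figures were drawn with matplotlib 3.10.9.

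The gene lists, the tests of the collagen comparison, the rule for named genes and all alternatives but 4 were fixed before the data were examined. The exceptions were chosen after seeing the data: removal of the channel component, flag C spots alone, fry in either direction, and an estimated correlation for the lists of the channel component. As fewer than 20 probes passed, the rule took the 12 genes higher and the 12 lower with the smallest p among those with 1 gene symbol and 1 sign on all 6 arrays. It added 16 genes set in advance, and 4 members from each of the 4 lists with the smallest camera p. These 4 members had the smallest p among those that moved in the direction of the list. Alternatives covered background, normalisation within and between arrays, dim spots, the authors' values, single scans, fits of the 6 arrays with the replicate as a block, single dye orientations, the variance model, thresholds and each replicate left out. The arrays that share a replicate number come from the same pair of RNA samples per the series' design, which is where the pairing comes from. Their turned ratios correlated below 0, with a consensus correlation of −0.22 without a dye term and −0.07 with one.

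The fit was tested on simulated data made from the 6356 probes, their spread and their channel component, with 200 probes changed. It recovered 44.8% of 67 probes changed by 0.5 log2, 100% of 67 changed by 1 log2 and 100% of 66 changed by 2 log2. It called 168 probes in all, 5 of them unchanged ones. The score beyond 2 local SD recovered 2.99%, 76.1% and 100% of the same probes. A list of 21 genes moved by 0.25 log2 passed camera, and 1 other list passed too. Some lists share genes with the moved one, so that other list may hold moved genes. The simulation draws genes independently, so it says nothing of correlated noise. It gives both arrays of a swap the same dye effect, so it says nothing of an unequal one. Its 200 changed probes ease the adjustment, so the recovery of a lone change was not measured.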

Results

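Gene expression was compared in the midbrain of C57Bl/6 mice given type II collagen to induce arthritis and of control mice. All mice were males of 8 weeks. The collagen mice received 100 µl of type II collagen in 100 µl of complete Freund's adjuvant, an oil emulsion with killed mycobacteria that provokes strong immunity, and the control mice received 200 µl of the adjuvant alone. Both arms were given lipopolysaccharide (LPS), a bacterial cell wall component that activates innate immunity, at day 24. The arms thus differed in adjuvant volume as well as in collagen, and the comparison cannot separate these. No arm went without adjuvant or LPS. Each of 6 two-colour arrays held 1 collagen RNA and 1 control RNA, as 3 biological replicates hybridised a second time with the dyes exchanged. In the group collagen_in_Cy5 the collagen RNA carried Cy5, and in the group collagen_in_Cy3 it carried Cy3, with 3 arrays in each. Whether a replicate was a single mouse or a pool is not given in the sources used here.

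Each array carried 10080 spots, of which 8776 to 9786 gave a signal in both channels in at least 1 scan. Among spots with a corrected intensity above 0 in the channel, the median stood at 1.82 to 5.68 times local background in channel A. In channel B it was 2.51 to 3.96 times, both over the 16 scans. A total of 6356 probes were measured on all 6 arrays, and 5738 of these had 1 gene symbol, for 5611 genes. Ratios are given as log2 of collagen over control, as the mean over the 3 replicates with each dye swap averaged. The direction is likely and not settled. Channel A of the scans was taken as Cy3, the dye that the labels list as channel 1, and every sign below would turn if channel A held Cy5. The number of arrays limits the precision: the median probe had a standard error (SE) of 0.14 and a 95% interval of 0.32 to either side.

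The first question was which genes differed in the midbrain of collagen mice. No gene passed the test in either direction: 0 probes were higher and 0 lower by limma's moderated test after Benjamini-Hochberg adjustment, with a smallest adjusted p of 0.944. At an unadjusted p under 0.05 there were 291 probes, of which 198 were higher and 93 lower, against 317.8 that chance alone gives among 6356. With the channel component removed from each array, a setting chosen after seeing the data, that count was 350 by the same test. The shortfall thus depended on the processing, and 0 probes passed after adjustment in that setting too. Fits of the 6 separate arrays with the replicate as a block also called 0 probes, with a dye term or without one. Ratios were small throughout, and 98.8% of the probes lay within 0.5 log2 of equality. This does not show that the tissues were alike. The averaging of swapped arrays takes the dyes to have been exchanged as labelled; had they not been, it would cancel a collagen effect and the count of 0 would set no limit. With the dyes exchanged, simulated changes of 1 log2 were all recovered by the same fit over 6356 probes. Those of 0.5 log2 were recovered for 44.8% of the probes. The simulation changed 200 probes at once, which eases the adjustment, and gave both swapped arrays the same dye effect. It therefore does not show that a change in a single probe would have passed. The count of 0 held for both directions in each reprocessing that kept all 3 replicates and both dyes at the adjusted threshold. Without replicate 3, 1 probe was called higher, for Kdm5d, a histone demethylase gene of the Y chromosome, and its ratio in replicate 3 was −0.38.

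Among the genes with 1 sign on all 6 arrays, the strongest evidence was for a lower level of Pmch, although it did not pass over all probes. Pmch encodes the precursor of melanin-concentrating hormone, a neuropeptide of the lateral hypothalamus. Its log2 ratio was −0.65 (SE 0.13, n = 3), or 1.57-fold lower, with replicates at −0.80, −0.64 and −0.51 and an adjusted p of 0.944. Nt5c3b, a nucleotidase gene, had a ratio of −0.63 (SE 0.15). Gpr63, which encodes an orphan receptor, stood at −0.52 (SE 0.16), and 1500009C09Rik at −0.47 (SE 0.14). Clint1, whose product takes part in clathrin-coated vesicle traffic, was at −0.44 (SE 0.13), and Gltp, the glycolipid transfer protein gene, at −0.41 (SE 0.13). Col27a1, a fibrillar collagen gene, was at −0.40 (SE 0.13). Irak3, an inhibitor of Toll-like and interleukin-1 receptor signalling, was at −0.34 (SE 0.14). Completing the 12 ranked lower, Stk32c, Lrrcc1, Wdr73 and 1700012P22Rik had ratios of −0.38, −0.37, −0.35 and −0.34. None of the 12 passed, and they are given as ranked and not as changed. With the authors' deposited log ratios, whose scale is unknown, Pmch was at −0.41, Nt5c3b at −0.25, Lrrcc1 and Col27a1 at −0.13 and −0.14, and Gpr63 at −0.11. Over the alternative settings the weakest ratios were −0.16 for Irak3, −0.11 for Wdr73, −0.22 for Gltp and −0.25 for Clint1.

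On the other side, 8430431K14Rik ranked first with a log2 ratio of 0.57 (SE 0.13, n = 3), or 1.49-fold higher. Its replicates stood at 0.67, 0.52 and 0.54, with an adjusted p of 0.944. Trim34a, of an interferon-inducible family, had a ratio of 0.50 (SE 0.14). Ikzf1, which encodes the lymphoid transcription factor Ikaros, was at 0.44 (SE 0.14). Hgf, the hepatocyte growth factor gene, was at 0.46 (SE 0.15), and Il34, a ligand of the colony-stimulating factor 1 receptor on microglia, at 0.40 (SE 0.14). Gsto2, a glutathione transferase gene, was at 0.44 (SE 0.13). Nipa2, which encodes a magnesium transporter, was at 0.47 (SE 0.14). Sec11a, of the signal peptidase, was at 0.43 (SE 0.15), and Rnf167, a ubiquitin ligase gene, at 0.40 (SE 0.13). For 4930453N24Rik, Fibin and Prr32 the ratios were 0.52, 0.50 and 0.36. In Fibin the mean rested on replicate 2, at 1.08 against 0.22 in each of the others, and in 4930453N24Rik replicate 3 was at 0.08. Replicate 2 also stood out in Hgf, at 0.82 against 0.25 and 0.31, and in Sec11a, at 0.76 against 0.33 and 0.20. For Hgf the arrays of replicate 2 were at 1.59 with collagen in Cy5 and 0.05 with collagen in Cy3. In Trim34a the collagen_in_Cy5 arrays of replicates 1, 2 and 3 were at 0.23, 0.10 and 0.06, and the collagen_in_Cy3 arrays at 1.01, 1.21 and 0.41. These 12 did not pass either. With the authors' deposited log ratios Nipa2 was at 0.069 and Rnf167 at 0.23. The weakest ratios over the alternative settings were 0.13 for Trim34a, 0.13 for 4930453N24Rik and 0.064 for Hgf. In all, 144 of the 6356 probes, or 2.27%, had 1 sign on the 6 arrays, 62 higher and 82 lower, where independent signs give 3.125%. The signs were not independent, because the turned ratios of swapped arrays correlated below 0, at −0.33 on average. The lower share therefore says nothing for or against a collagen effect.

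**Figure D1:**
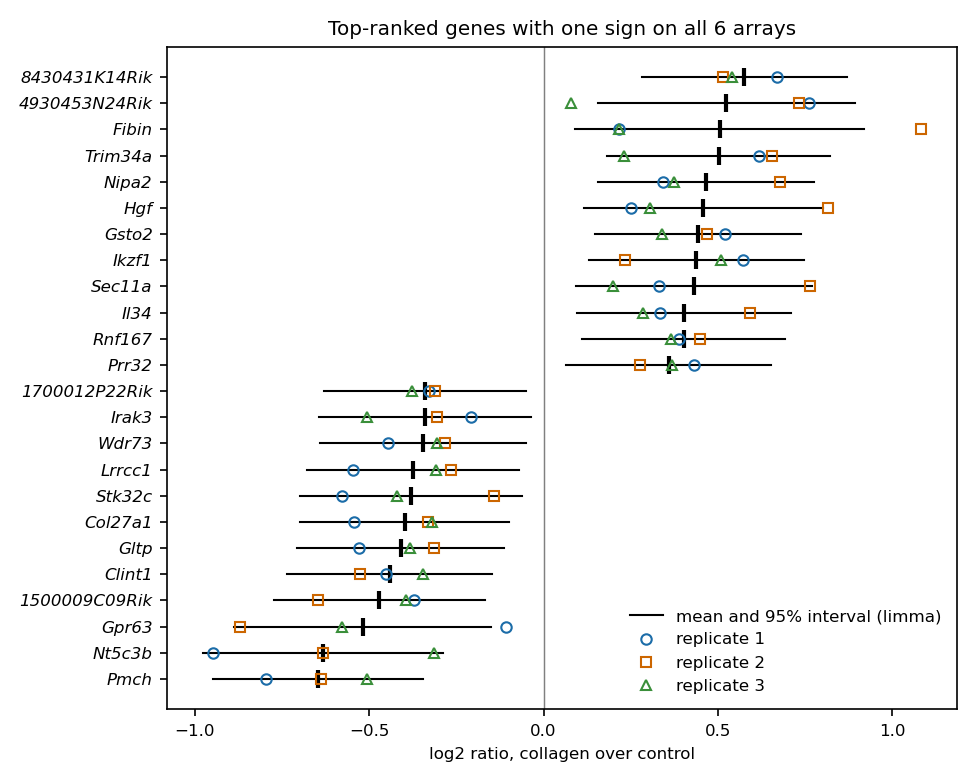
Log2 ratio of collagen over control for the 24 top-ranked genes with 1 sign on all 6 arrays. Open symbols are the 3 replicates (each the mean of its dye swap), and the vertical tick and horizontal line are the limma mean and 95% interval; Pmch, at −0.65, lies farthest from 0, and no gene passed after adjustment.

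Several genes were named in advance for their bearing on arthritis, LPS or the midbrain. Th, which encodes tyrosine hydroxylase of dopamine synthesis, had a ratio of 0.16 (SE 0.16, n = 3) and an adjusted p of 0.953. Aif1, a microglial marker, was at 0.02 (SE 0.14). Lcn2, an acute phase gene that binds bacterial siderophores, was at 0.36 (SE 0.14), higher on 5 of 6 arrays, with an adjusted p of 0.944. Fos, an activity-induced transcription factor gene, was at 0.46 (SE 0.17), but higher on 3 of 6 arrays, with an adjusted p of 0.944. Il1b, Il6 and Fkbp5 were measured on 5 of 6 arrays and were not tested. Over the replicates with both arrays, 2 for each gene, their mean ratios were −0.20 ± 0.01, 0.15 ± 0.45 and −0.08 ± 0.10 (SD, n = 2). The other 9 of the 16 genes have no probe named for them in the probe table used here.

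Gene groups set in advance were then compared with all other genes. Of 34 lists, 29 had 5 or more measured members, and 0 passed with camera, limma's competitive test for gene lists, at a smallest adjusted p of 0.298. With an estimated correlation between genes 0 passed as well, and the rotation test fry, which compares a list with no change, gave 0 for movement in 1 direction. In its form for change in either direction fry gave 1, the hypothalamus list at an adjusted p of 0.0357. At an unadjusted p under 0.05 camera gave 4 lists, which are described with their members. Over the 321 measured list genes, 0 passed the test over all genes, and 1 gene passed when adjusted over the list alone, Pmch in the hypothalamus list at an adjusted p of 0.0073. Adjusted over all 321 list genes together, its adjusted p was 0.261.

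Most measured members of several innate immune and activity-related groups were higher in collagen, but no such group passed. Of 21 measured genes of the acute phase and LPS response, 14 were higher and 7 lower, with a median of 0.09 and an adjusted p of 0.298 (0.938 with an estimated correlation). The 4 members named by rule had the smallest p among those higher. Lcn2 was at 0.36 and the ferroxidase gene Cp at 0.27 (SE 0.15). The cytokine signalling inhibitor gene Socs3 was at 0.26 (SE 0.16) and the LPS co-receptor gene Cd14 at 0.21 (SE 0.13). Replicates of Cp were at 0.54, 0.04 and 0.24 and those of Socs3 at 0.24, −0.11 and 0.64, and Cd14 was higher on 3 of 6 arrays. Among the lower members, Tlr4 at −0.29 (SE 0.14) had a smaller p than all of these but Lcn2. Of 8 immediate early genes 7 were higher, with a median of 0.13 and an adjusted p of 0.298 (0.938 with an estimated correlation). Besides Fos at 0.46, Fosb was at 0.23 (SE 0.19), Egr2 at 0.18 (SE 0.14) and Nr4a3 at 0.18 (SE 0.26). Averaged over the 6 arrays, channel B over channel A stood at −0.96 for Fos, −0.85 for Fosb, −0.22 for Egr2 and −2.10 for Nr4a3, though these channel components did not pass, with adjusted p of 0.293, 0.401, 0.602 and 0.101. In replicate 3 all 4 were below 0. With loess within printing blocks Fosb was at −0.11 and Nr4a3 at −0.72, and with the authors' values Nr4a3 was at −0.39. Among interferon-stimulated genes 7 of 11 were higher, with a median of 0.15 and an adjusted p of 0.390. Glucocorticoid-induced genes were higher in 6 of 9, with an adjusted p of 0.690. Cytokines, chemokines and their receptors split into 13 higher and 9 lower of 22, at an adjusted p of 0.984. Complement and coagulation genes split into 3 and 3, at 0.984.

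Of the cell type marker lists, none passed. Oligodendrocyte and myelin genes were higher in 5 of 7, with a median of 0.01 against a mean of 0.13, a median of −0.05 in replicate 2 and an adjusted p of 0.298 (0.938 with an estimated correlation). Sox10, the lineage transcription factor, was at 0.38 (SE 0.15) and Gal3st1, of sulfatide synthesis, at 0.39 (SE 0.15). Their replicates 1, 2 and 3 were at 0.66, 0.16 and 0.30 for Sox10 and at 0.40, 0.67 and 0.09 for Gal3st1. Cryab, a small heat shock protein gene, was at 0.21 (SE 0.16) and Ugt8a, of galactosylceramide synthesis, at 0.01 (SE 0.14). Microglial markers were higher in 10 of 12, with a median of 0.06 and an adjusted p of 0.575. Endothelial genes were higher in 6 of 8 and pericyte and smooth muscle genes in 2 of 6, both with an adjusted p of 0.984. Choroid plexus and ependyma genes were higher in 5 of 8 (adjusted p of 0.922), and meningeal and fibroblast genes in 4 of 7 (adjusted p of 0.472). For blood cells, lymphocyte markers were higher in 5 of 9 and neutrophil and monocyte markers in 5 of 7, both at an adjusted p of 0.984. General neuronal genes were higher in 5 of 12 (adjusted p of 0.987) and dopaminergic genes in 7 of 12 (adjusted p of 0.690). Astrocyte, serotonergic, MHC class I, MHC class II and erythrocyte lists had 4, 4, 2, 1 and 1 measured members, of which 2, 2, 1, 0 and 1 were higher, and were not tested. Of the neighbouring tissues, hypothalamic genes were lower in 6 of 9 (adjusted p of 0.390), and those of hippocampus, thalamus and cortex in 4 of 7 (adjusted p of 0.965). Pituitary genes were lower in 3 of 6 and cerebellar genes in 4 of 6, both at an adjusted p of 0.984.

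In the groups for cell metabolism and signalling, proteasome genes were lower in 11 of 13, with a median of −0.09 and an adjusted p of 0.298 (0.938 with an estimated correlation). Psma4, of the core particle, was at −0.25 (SE 0.16), and Psmc3, Psmd7 and Psmc1, of the regulatory particle, were at −0.23, −0.21 and −0.16 (SE 0.14 each). Psma4 was at 0.13 in replicate 1, and in replicate 3 Psmd7 was at 0.007 and Psmc1 at 0.04. The list medians in replicates 1, 2 and 3 were −0.13, −0.24 and 0.008. Oxidative phosphorylation genes were lower in 19 of 29 (adjusted p of 0.472), cholesterol biosynthesis genes in 5 of 6 (adjusted p of 0.690) and cytosolic ribosome genes in 12 of 26 (adjusted p of 0.922). Synaptic vesicle genes were lower in 9 of 13 (adjusted p of 0.551), and potassium and sodium channel genes in 8 of 11 (adjusted p of 0.575). Genes of GABA and glutamate transmission were lower in 7 of 13, those of opioid and pain neuropeptides in 8 of 16, and those of heat shock and unfolded protein response in 7 of 12, all with an adjusted p of 0.984. In 8 of the 29 lists the median, the mean and the direction of the test differed in sign, all with an adjusted p of 0.984 or above. These were pericyte and smooth muscle, general neuron, opioid and pain neuropeptides, cytokines, neutrophil and monocyte, pituitary, cerebellum, and heat shock.

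**Figure D2:**
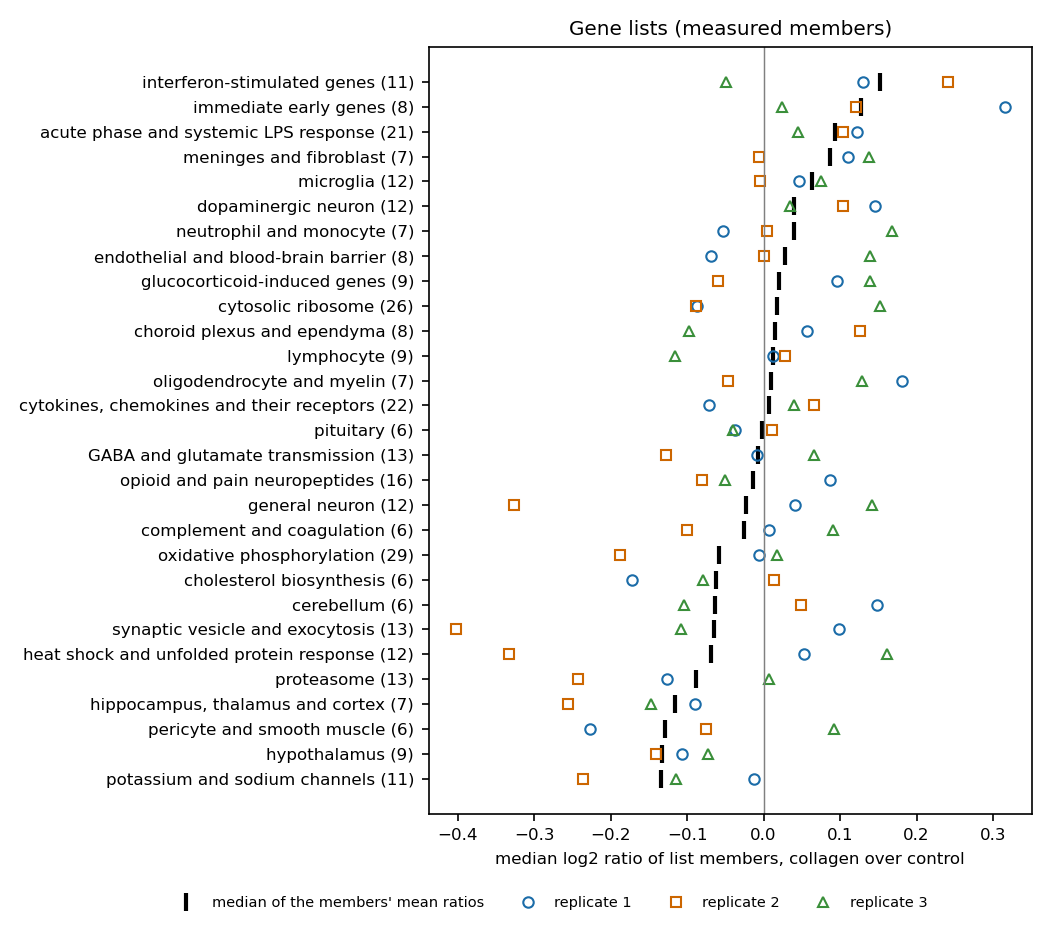
Median log2 ratio of collagen over control in each of the 29 tested gene lists, with the number of measured members in brackets. Open symbols are the medians in the 3 replicates and ticks the median of the members' means; the replicate medians fall on both sides of 0 in most lists, and 0 lists passed camera.

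A final comparison asked how far the ratios followed the RNA, the dye or the replicate, by Pearson correlation across probes, which are not independent replicates. Once turned to collagen over control, the 2 arrays of a dye swap should correlate above 0 if RNA differences dominate and the dyes were exchanged as labelled. They correlated at −0.31, −0.48 and −0.21 in replicates 1, 2 and 3. As ratios of channel B over channel A, all 15 pairs of arrays correlated above 0, at 0.06 to 0.55. The replicate means correlated at 0.14 between replicates 1 and 2, at −0.07 between 1 and 3 and at −0.03 between 2 and 3. The part of the log ratio that stayed with the channel had an SD of 0.34 over probes, against 0.18 for the collagen ratio, and 54 probes passed limma's test for it at an adjusted p under 0.05. All 54 were brighter in channel A. That count depended on which replicates were kept, at 16 without replicate 1, 87 without replicate 2 and 291 without replicate 3. It was 12 with the authors' values. As lists, ribosomal and oxidative phosphorylation genes leaned to channel B at a camera adjusted p of 0.0092 each with the preset correlation, but 0 lists passed with an estimated one, at a smallest adjusted p of 0.983. As intensity-dependent scores, 0 probes lay beyond 2 local SD in 1 direction in all 3 replicates. With replicate 3 turned, 3 probes did so, and with replicate 2 or replicate 1 turned, 0.

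**Figure D3:**
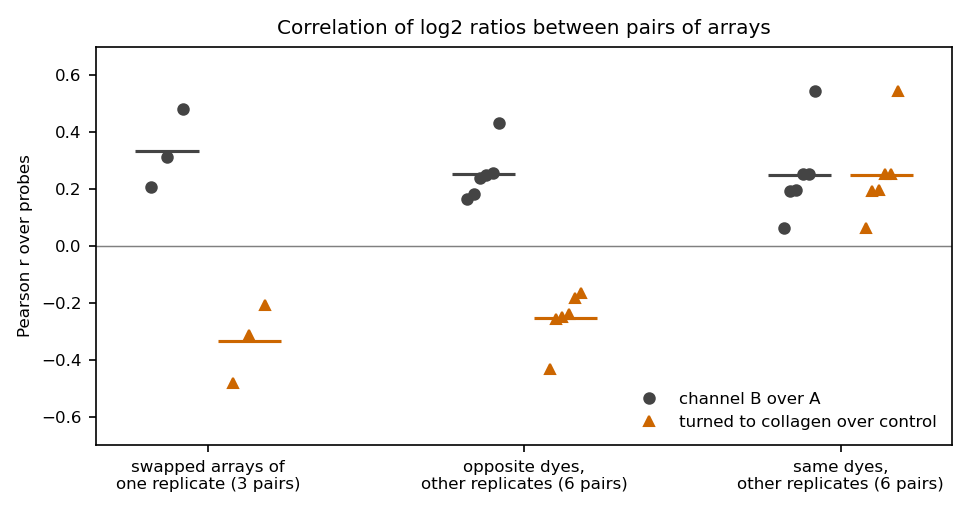
Pearson correlation of log2 ratios over probes for the 15 pairs of arrays. Circles are ratios of channel B over channel A and triangles the same arrays turned to collagen over control, with bars at the means; the 3 swapped pairs average 0.33 before turning and −0.33 after it.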

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

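The tests of printing blocks, of exchanged dyes and of a channel effect particular to each probe were chosen after the correlations between arrays were seen. The test on bright probes was set before its result was seen. For 54 probes the collagen ratio differed between the 2 dye orientations at an adjusted p under 0.05 by limma's test of the difference. Of these, 29 had 1 gene symbol, among them 1 probe of Kcnma1, and none was among the genes named by the rule set in advance. Their mean log2 ratios of channel B over channel A ran from −2.96 to −0.89.

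The pattern was that log ratios followed the scanner channel and not the RNA as labelled. Weak signal is argued against, because swapped arrays turned to collagen over control correlated at −0.54 on average over the brightest 25% of probes, farther from 0 than the −0.33 over all probes. Differences between printing blocks are argued against as the whole of it, since the mean stayed at −0.26 after loess within blocks. A channel effect particular to each probe remains a candidate explanation for a part of it: arrays of other replicates and opposite dyes also correlated above 0 in all 6 pairs, at 0.25 on average. The mean of the turned swaps stayed at −0.40 to −0.23 in 14 settings, which include removal of the channel component from each array. That removal takes out only what the arrays of the other replicates share, and the cause of the remainder was not tested. Whether the dyes were truly exchanged within each replicate cannot be told apart from a channel effect, because the unturned correlation within swaps, 0.33, lay inside the range between replicates. Without that exchange, the averaging of swapped arrays would cancel any collagen effect. No biological explanation was tested.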

How the results depend on the processing

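The settings that remove the channel component, keep only spots with flag C, test lists with fry in either direction or estimate the correlation for channel lists were chosen after seeing the data. Of 21 settings that give a count of probes called, 18 gave 0 in both directions. Fits with the replicate as a block called 0 higher and 0 lower, with a dye term or without. The collagen_in_Cy5 arrays alone, where dye and RNA are confounded by construction, gave 38 lower probes, 38 probes beyond 2 local SD, 1 list (cytosolic ribosome) and a replicate correlation of 0.17. The collagen_in_Cy3 arrays alone gave 56 probes beyond 2 local SD, 2 lists (hypothalamus and oxidative phosphorylation) and a correlation of 0.33. At an unadjusted p under 0.01 there were 29 higher and 10 lower probes, fewer than the 63.6 of chance.

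Probes beyond 2 local SD numbered 0 in the main setting, 1 with normexp, 2 with median centring only, 1 with Aquantile (which changes intensities and no ratio), 7 at 1.5 local SD and 1 with an SD over the whole array. Their number was 6 to 46 with 1 replicate left out, where fewer replicates must concur. Leaving out a replicate gave 0 to 1 probes higher and a mean replicate correlation of −0.066 to 0.14, both highest without replicate 3. The 1 probe was Kdm5d, at 1.39 without replicate 3. With the authors' values 1 list passed, GABA and glutamate transmission at an adjusted p of 0.0142 over 9 measured genes; the cause was not tested. With fry in either direction 1 list passed, hypothalamus at 0.0357, and over the other settings that keep both dyes 0 lists passed. Probes with a channel component, 54 in the main setting, numbered 27 without background subtraction, 92 with normexp and 12 with the authors' values. With 1 replicate left out they numbered 16 to 291, at 16 without replicate 1, 87 without replicate 2 and 291 without replicate 3. The cause was not tested. The mean correlation of turned dye swaps lay at −0.40 to −0.23 in the 14 settings that give one.

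The 24 ranked genes were chosen for 1 sign on all 6 arrays, so that most settings could not turn it. Among settings that recompute ratios, 15 of 24 moved by 1 SD between replicates or more with normexp, 10 of 24 with loess within printing blocks, 7 of 24 without background subtraction and 7 of the 10 tested with the authors' values. Over all 42 named genes 20 of 736 values changed sign. Only Nr4a3 reversed at an adjusted p under 0.05, at −1.93 on the collagen_in_Cy5 arrays alone. Keeping rejected spots was not run, because they carry no intensity. Signal over background limited 94 of the 6356 probes, which fell short of 1.5 times background on some array, and leaving them out gave 0 calls.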

Other observations

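The test of replicate turning after removal of the channel component and both tests on Pmch were set before their results were seen, and the count of sign patterns after. In the hypothalamus list the members went both ways. Trh was at −0.27 (SE 0.13), Avp at −0.21 (SE 0.13), Otp at −0.14 (SE 0.13) and Oxt at −0.13 (SE 0.14), while Sst stood at 0.30 (SE 0.16) and Hdc at 0.17 (SE 0.13). Pdyn, an opioid peptide gene, was at −0.38 (SE 0.15), and Tlr4, the LPS receptor gene, was lower on all 6 arrays at −0.29 (SE 0.14). These were chosen after their values were seen, and none passed over all probes. Different probes of a gene did not concur. Over 117 genes with 2 tested probes, the collagen ratios correlated at 0.01 and the mean intensities at 0.28. Kcnma1, for example, had probes at 0.85 and −0.44, the first with a channel component of −1.30 that passed at an adjusted p of 0.0218.

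Pmch was lower on all 6 arrays, at −0.65. With the channel component removed from each array the ratio was −0.63 (SE 0.13), with an adjusted p of 0.842 by limma. This cannot decide on an unequal dye effect. The channel component of Pmch was only 0.12, so its removal could hardly move the ratio, and the gene was picked for 1 sign on all 6 arrays. Less lateral hypothalamus in the dissected collagen tissue stays open. Hcrt, made in the same area, was measured on 5 arrays, and its 2 complete replicates gave 0.43 and −0.16, a mean of 0.13 (SE 0.29) that decides nothing. A change of Pmch in the neurons themselves was not tested, and the gene stands as a hypothesis from 1 probe.

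Replicates 1 and 2 correlated weakly with each other, at 0.14, and with replicate 3 at −0.07 and −0.03. Turning replicate 3 gave 122 probes at an unadjusted p under 0.01, against 39 with no replicate turned. A candidate explanation is a dye effect of unequal size on the 2 arrays of a replicate, which averaging does not cancel. The replicate means correlated with the channel component of the other replicates at −0.31, −0.26 and 0.12 in replicates 1, 2 and 3. With that component removed, the count with replicate 3 turned was 61 and that with none turned 54, and replicates 1 and 2 correlated at 0.07 in place of 0.14. For the count of 0 probes past the threshold, the 3 replicates allow 4 sign patterns, too few for a share under 0.05. All 4 gave 0, the highest of the others being 0.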
